A study of Mus musculus with 48 samples.

How the data were processed

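Read counts per gene symbol were taken as deposited, for 24328 symbols in 48 libraries. According to the notes with the samples, RNA was purified with a Qiagen kit, libraries were made with the Clontech SMARTer chemistry, read quality was examined with FastQC and reads were aligned with STAR 2.5.0 to the mouse genome build mm9. The strand setting, the annotation release and the counting program are not given in the sources used, so antisense genes and overlapping neighbours share an unknown part of their reads. The tables carry symbols and no coordinates, so genes are named by symbol. Reads of close relatives (the Klra, Klrb1 and granzyme families, and ribosomal protein genes with their processed pseudogenes) can be counted for each other, and the folds of single members carry that limit. The counts are whole numbers, and the 60 pairs of libraries within a group held 0 identical pairs, with a chi-square per degree of freedom of 7.34 to 84.9 over genes with at least 20 counts.

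The 3 experiments were fitted apart, since no group is common to them. Genes were kept by the filterByExpr rule, which left 12258 genes in the conditional experiment, 11051 in the WT subsets and 10614 in the chimeras. Libraries were scaled by TMM factors, which ran from 0.833 to 1.16, from 0.955 to 1.08 and from 0.900 to 1.10. The common biological coefficient of variation was 0.173, 0.229 and 0.148 in that order. The edgeR 4.0.16 quasi-likelihood F test with robust dispersions was used on R 4.3.3, with 16, 12 and 6 residual degrees of freedom. All p-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given ± SE and levels as mean CPM ± SD (read counts scaled to a common library total), where n is 3 libraries per group in the conditional experiment and 4 in the others. The labels do not state that replicate numbers mark single animals, so the p-values measure the spread between samples. A count of 3 in 1 library, used as the detection floor, stands for 0.143 to 0.220 CPM in the conditional libraries, 0.252 to 0.334 CPM in the WT subsets and 0.232 to 0.351 CPM in the chimeras. Floors cover counting error only, intervals of folds come from the SE and hold the spread between libraries, intervals of medians are bootstraps over genes, which are not independent, and intervals of shares of calls are exact binomial. Where a group held 3 counts or fewer for a gene, its levels are given without a fold.

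The comparisons, the tests, 22 gene lists and the rule for naming genes were chosen before the data were examined. Open to naming in each comparison were Bach2, 15 core NK genes, and the 5 higher and 5 lower called genes with the largest fold change that reached 5 CPM in the higher group and whose libraries did not overlap between the groups. Predicted genes, small RNA genes and immunoglobulin or T cell receptor segments were left out of that choice, and the words largest and most refer to genes under this rule. The text prints a part of these genes, and the plot of core genes shows Bach2 and all 15 in the knockout comparisons. As examples of a list, up to 2 higher and 2 lower called members with the smallest p are named, or, where no member passed, up to 2 with the highest expression. Lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01, adjusted over the 22 lists of a comparison, and again with a correlation estimated from the data. The lists share members: Gzmb, for example, stands on the core, cytotoxic and late maturation lists. The maturation sets are the genes that differed by 2-fold or more between the KLRG1-positive mNK2 and the iNK libraries of the WT experiment, and they were tested in the same way. Overlaps of calls were tested with the 2-sided Fisher's exact test, adjusted over 20 tests.

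Whether equal replicate numbers mark a shared animal was examined by the correlation of residuals between libraries of the same number. It exceeded 0.1 for every pair only between cWT iNK and cWT NK, where it ran from 0.185 to 0.353, so a fit with the replicate number as a block is reported beside that comparison. In the chimeras, and where KLRG1-negative mNK2 was compared with mNK1 or KLRG1-positive mNK2, all 8 libraries correlated best with their own number. The cut of 0.1 therefore does not show these to be unpaired. Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, RLE factors, no low-count filter, a filter at 5 CPM, a replicate block, a fit of only the 2 groups compared, and each library left out in turn. RLE factors, or leaving out the ribosomal RNA gene Rn45s, shifted the fold changes of a comparison by at most 0.0206 (log2).

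Counts were simulated with the same design and 200 changed genes, drawn only from genes at a mean of 5 CPM or more. The edgeR test recovered 49.3% of 1.5-fold, 76.1% of 2-fold and 98.5% of 4-fold changes for the conditional NK comparison, with 3 false calls. Recovery below 5 CPM was not simulated. For the WT step from iNK to mNK1 the shares were 38.8%, 70.1% and 98.5% with 7 false calls, and for the chimeras 61.2%, 94.0% and 100% with 7. Of 100 random lists, 3, 2 and 5 passed an unadjusted camera p of 0.05. The simulated genes were drawn independently of each other, so these numbers do not test the preset correlation of 0.01. An interaction of 4-fold, simulated as a rise in mNK2 alone in genes of the same level, was recovered for 92% of genes with 8 false calls.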

Results

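RNA-seq read counts per gene were measured in 48 libraries of natural killer (NK) cells sorted from mouse spleens, which fall into 14 groups from 3 experiments. The conditional experiment holds 24 libraries. Its control animals (cWT) carry Cre recombinase expressed from Ncr1, a gene active in NK cells, and its cKO animals carry in addition loxP-flanked alleles of Bach2, which encodes a transcriptional repressor of the bZIP family. Each genotype was sorted into 4 fractions labelled NK, iNK, mNK1 and mNK2, with 3 libraries per fraction. The WT subset experiment holds 16 libraries of unmodified animals, 4 each for iNK, mNK1, KLRG1-negative mNK2 and KLRG1-positive mNK2, where KLRG1 is an inhibitory receptor of mature NK cells. The chimera experiment holds 4 WT and 4 Bach2-KO libraries of unfractionated NK cells from hosts given a mixture of both marrows, so that WT and KO cells matured in the same animals. By the usual naming iNK stands for immature and mNK for mature NK cells, but the surface markers of the gates, and whether the fraction labelled NK is the unfractionated population, are not given.

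Total counts per library ran from 13650636 to 21029172 in the conditional experiment, from 8973777 to 11924274 in the WT subsets and from 8557018 to 12927472 in the chimeras. Counts were seen for 13432 to 14342, 11795 to 12674 and 12653 to 13171 genes per library in that order. The pre-ribosomal RNA gene Rn45s took 0.0890% to 0.360% of the counts in the conditional libraries, against 18.6% to 29.1% in the WT subsets and 20% to 25.8% in the chimeras. In the conditional experiment the first principal component held 59.7% of the variance and the next 16.4%, and the libraries lay together by fraction rather than by genotype.

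**Figure D1:**
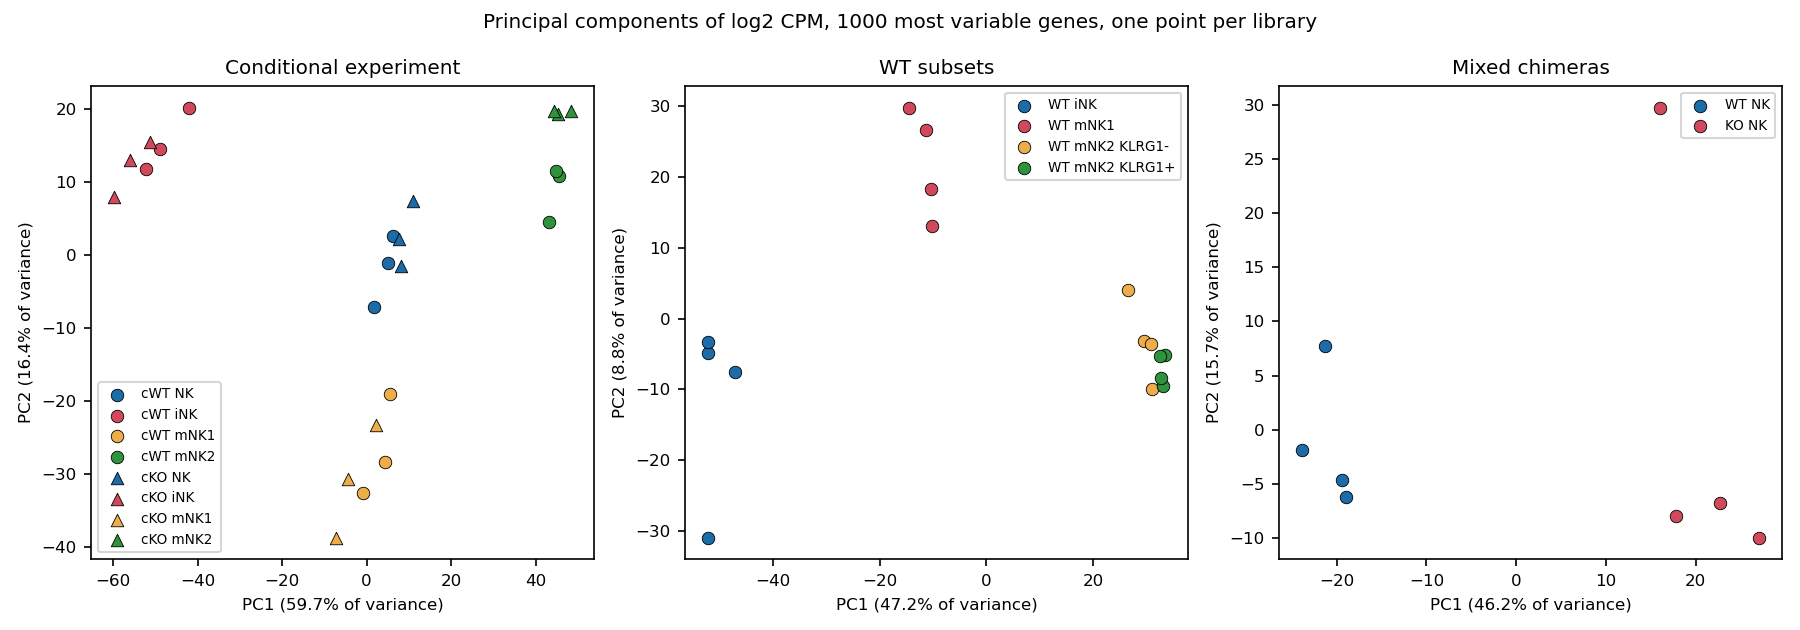
Principal components of log2 CPM over the 1000 most variable genes in each experiment, each point a library, coloured by fraction or group (triangles are libraries labelled cKO). Along the component that holds 59.7% of the variance in the conditional experiment, iNK and mNK2 lie on opposite sides of NK and mNK1, which part along the component that holds 16.4%.

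Bach2 itself was measured to ask how far its transcript was lost. In the chimeras it fell from 15.5 ± 2.21 CPM in the WT libraries to 2.11 ± 0.927 CPM in the KO libraries (SD, n = 4), a log2 fold change of -2.89 ± 0.27 with an edgeR adjusted p of 2.74e-07. In the conditional experiment no fraction showed a fall. The mean levels were higher in the libraries labelled cKO than in cWT, at 20.9 ± 2.38 against 13.9 ± 4.53 CPM in NK and 19.6 ± 3.66 against 13.5 ± 2.16 CPM in iNK (SD, n = 3). In mNK1 they were 25.2 ± 5.35 against 13.5 ± 2.86 CPM and in mNK2 19.3 ± 4.85 against 11.9 ± 1.35 CPM. None of these differences passed the edgeR test adjusted over all genes (adjusted p = 0.375, 0.552, 0.0776 and 0.442). The one in mNK1 did pass with the replicate number as a block (adjusted p = 0.0131). For Bach2 alone, a gene chosen beforehand, the unadjusted edgeR p was 0.0155, 0.026, 0.000563 and 0.00573 in NK, iNK, mNK1 and mNK2. Counts of a whole gene do not show whether a single exon is missing, and the labels do not say which part of Bach2 is flanked by loxP sites. Directions in the conditional comparisons are therefore those of the libraries labelled cKO against those labelled cWT. Across the WT subsets Bach2 stood at 17.2 ± 5.81 CPM in iNK, 15.7 ± 3.52 in mNK1, 17.8 ± 6.95 in KLRG1-negative and 15.4 ± 3.64 in KLRG1-positive mNK2, with no step past the test.

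**Figure D2:**
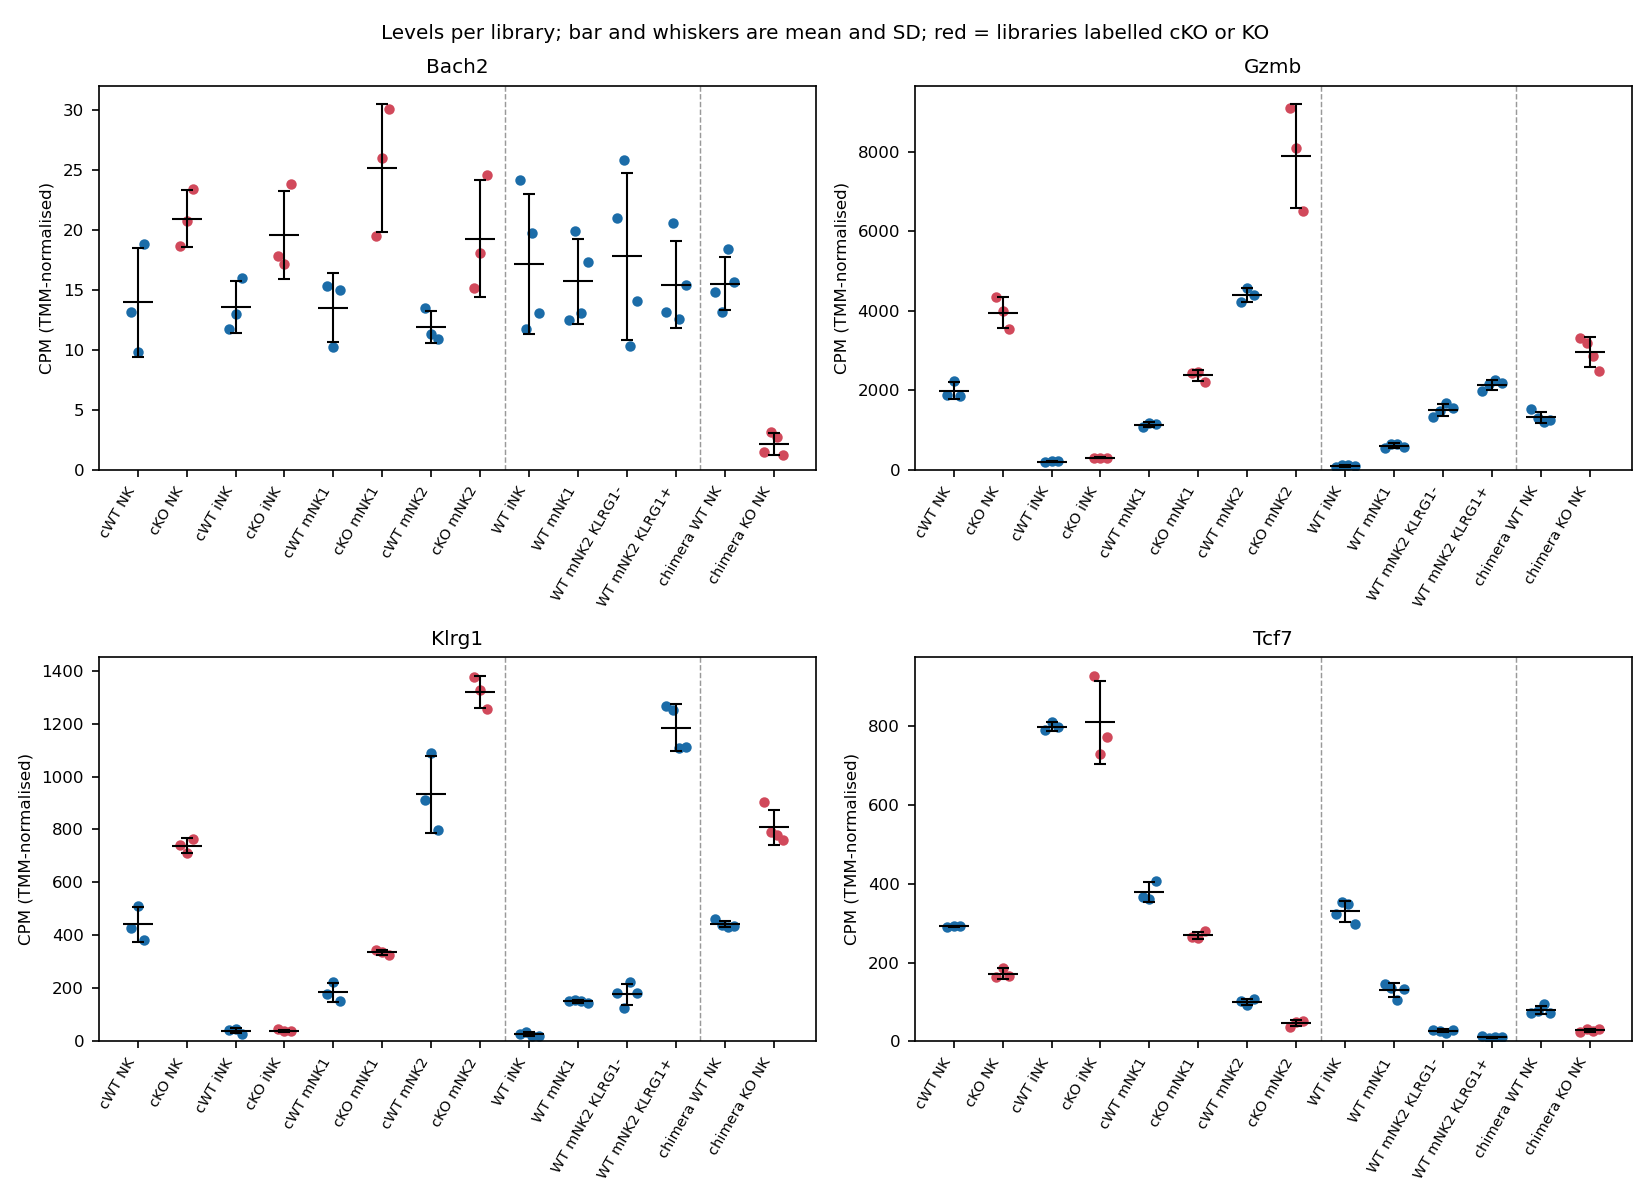
Levels of Bach2, Gzmb, Klrg1 and Tcf7 in CPM (vertical axis) by group, each point a library, with mean and SD; red marks libraries labelled cKO or KO. Bach2 drops to 2.11 CPM only in the chimera KO libraries, while Gzmb is higher and Tcf7 lower in the chimera KO libraries than in their WT partners.

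The chimera comparison asks how NK cells without Bach2 differ from WT cells of the same hosts. The cells were not sorted into stages, so a changed mixture of NK stages and a change within cells cannot be told apart here. In the KO libraries Gzmb, the granule protease granzyme B, rose from 1315 ± 142 to 2959.5 ± 370.1 CPM (log2 fold change 1.17 ± 0.10, n = 4), and Klrg1 from 442 ± 12.1 to 808 ± 65.0 CPM (0.87 ± 0.07). Tcf7, a transcription factor of early and memory-like lymphocytes, fell from 79.4 ± 10.9 to 27.7 ± 3.09 CPM (-1.52 ± 0.11). Cd27, a surface marker of less mature NK cells, fell from 116 ± 16.7 to 66.6 ± 7.61 CPM (-0.81 ± 0.10). In each of these 4 genes the KO and WT libraries did not overlap, and the edgeR adjusted p ran from 1.18e-08 to 1.36e-05. Perforin (Prf1, 0.52 ± 0.10), Gzma (0.62 ± 0.15), Ifng (0.41 ± 0.10), the repressor gene Prdm1 (0.61 ± 0.10), Cx3cr1 (0.53 ± 0.09) and the integrin gene Itgam (0.30 ± 0.08) also rose. The master regulators Tbx21 (0.27 ± 0.08, adjusted p = 0.0690) and Eomes (-0.12 ± 0.07, adjusted p = 0.472), and Zeb2 (0.29 ± 0.17), S1pr5 (0.17 ± 0.08) and Il7r (-0.77 ± 0.36), did not pass. With the largest folds, the collagenase gene Mmp8 rose from 0.127 ± 0.150 to 6.66 ± 5.81 CPM, followed by Cyp11a1 (3.60 ± 0.32), C5ar1 (3.45 ± 0.39), Rab44 (3.45 ± 0.45) and Mmp9 (3.31 ± 0.47). On the other side stood the B cell genes Pou2af1 (-4.26 ± 0.50) and Fcmr (-4.04 ± 0.84), and Vipr1 (-3.76 ± 0.66). The kinase gene Camk2b fell from 57.4 ± 9.59 to 3.02 ± 0.892 CPM (-4.25 ± 0.19), one of 5 close neighbours on chromosome 11 among the 50 calls with the smallest p. In all, 531 of 10614 genes were called, 280 higher and 251 lower, of which 126 and 108 differed by 2-fold or more. Whether equal replicate numbers mark one host is not stated. All 8 libraries had their highest residual correlation with the library of their own number (0.0933 to 0.136), and with the number as a block 742 genes were called, all 531 among them. On the component that held 15.7% of the variance KO replicate 4 stood apart from the other KO libraries (29.8 against -9.98 to -6.77), and without it 672 genes were called.

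Of 19 early NK and stem-like genes tested in the chimeras 13 fell, with Ccr7 at -3.43 ± 0.38 beside Tcf7. Among 16 late maturation markers 8 rose and 2 fell, the latter Ly6c2 (-0.45 ± 0.08) and the integrin gene Itgax (-0.32 ± 0.08). Of 15 core NK genes 8 rose and 2 fell, and of 24 cytotoxic granule and effector genes 9 rose and 3 fell, with the chemokine gene Ccl4 at 0.79 ± 0.08 against Xcl1 at -1.07 ± 0.10 and Gzmm at -1.72 ± 0.19. Among 26 NK transcription factors 4 rose and 1 fell, with Irf8 (0.73 ± 0.09) and Rora (1.11 ± 0.16) higher and Tox (-0.38 ± 0.10) lower. On the heme and oxidative stress list, whose genes include targets of the related factor Bach1, 3 rose of 17, among them the antioxidant genes Prdx1 (0.42 ± 0.07) and Srxn1 (0.81 ± 0.15). The camera adjusted p of these 6 lists was 1.12e-14, 8.24e-07, 0.000688, 0.000957, 0.0391 and 0.000215, and with an estimated correlation the adjusted p was 0.0898, 0.0898, 0.210, 0.217, 0.408 and 0.150. The counts adjusted over the list alone were 15 lower for early NK genes, 9 higher and 2 lower for late maturation, 10 higher and 2 lower for core genes, 11 higher and 4 lower for cytotoxic genes, 8 higher and 2 lower for transcription factors and 8 higher for heme and oxidative stress. Camera also passed glycolysis (2 rose of 18), ribosomal protein (3 fell of 37) and cell cycle genes, where Rrm2 rose (0.50 ± 0.14) and 6 of 33 members were higher at an unadjusted p under 0.05. Their camera adjusted p was 0.0395, 3.00e-07 and 0.000730, and with an estimated correlation the adjusted p was 0.487, 0.217 and 0.307. Adjusted over the list alone, 3 higher and 2 lower for glycolysis and 10 lower for ribosomal proteins passed. With an estimated correlation 0 of the 13 lists past camera passed, the 4 lists of other cells included. The other 9 lists did not pass camera, among them the NK cell receptors (adjusted p = 0.354). On that list Klrb1b (1.31 ± 0.07) and Klra9 (0.91 ± 0.08) rose and Crtam (-1.54 ± 0.15) and Klra1 (-0.72 ± 0.10) fell.

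Markers of other cells moved in the chimeras too. Of 12 B cell markers 8 fell, with Cd79a going from 25.4 ± 13.4 to 2.04 ± 0.570 CPM. Of 10 T cell markers 5 fell, and Cd3e stood at 11.5 ± 3.82 and 1.46 ± 0.487 CPM in the WT and KO libraries. Of 10 neutrophil markers 5 rose, with S100a8 at 7.78 ± 6.56 CPM in the WT and 65.1 ± 38.4 CPM in the KO libraries. Of 9 myeloid and dendritic cell markers 4 rose, and Lyz2 stood at 13.8 ± 4.51 and 97.1 ± 55.3 CPM. The camera adjusted p of these 4 lists was 1.03e-14, 5.76e-09, 4.88e-12 and 2.80e-06, and with an estimated correlation the adjusted p was 0.115, 0.0898, 0.0898 and 0.115. Counts of members adjusted over the list alone were 12 lower for B cells, 7 lower for T cells, 10 higher for neutrophils and 7 higher for myeloid cells. Ccr7 and Fcmr among the lower genes and Mmp8, Mmp9 and C5ar1 among the higher ones are also expressed by such cells.

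The conditional experiment asks how NK cells differ under a deletion of Bach2 driven by Ncr1, a loss that the gene counts do not show. The NK fraction is compared first. If it is the unfractionated population, a changed mixture of NK stages may enter this comparison as well. In the libraries labelled cKO, Gzmb rose from 1992 ± 207 to 3952 ± 396 CPM (0.99 ± 0.10, n = 3, edgeR adjusted p = 1.53e-05) and Klrg1 from 442 ± 65.3 to 739 ± 28.0 CPM (0.74 ± 0.15, adjusted p = 0.0270). Tcf7 fell from 292 ± 1.65 to 172 ± 13 CPM (-0.77 ± 0.10, adjusted p = 0.000198) and so did Cd27 (-0.43 ± 0.08). Among the largest changes were higher Entpd1, which encodes the ectonucleotidase CD39 (1.09 ± 0.17), Ifi204 (1.15 ± 0.22), Trove2 (1.09 ± 0.24), Kcnj8 (1.09 ± 0.17) and Zbtb16, which encodes the innate lymphocyte factor PLZF (1.08 ± 0.24). Lower were Smyd2 (-1.29 ± 0.19), the ligand gene Tnfsf8 (-1.19 ± 0.20), the protease inhibitor gene Serpine2 (-1.18 ± 0.16), Capn3 (-1.16 ± 0.23) and the receptor gene Kit (-1.14 ± 0.22). Called were 70 of 12258 genes, 39 higher and 31 lower, 9 and 10 of them by 2-fold or more.

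Of 20 early NK and stem-like genes 5 fell in the NK fraction, Tcf7 among them, and of 16 late maturation markers 3 rose. Both lists passed camera (adjusted p = 1.39e-10 and 1.05e-07) and passed with an estimated correlation (adjusted p = 0.00770 and 0.0183). Of 15 core NK genes 2 rose and 2 fell, and of 24 cytotoxic genes 3 rose, with Serpinb9 at 0.44 ± 0.09. Irf8 rose among the NK transcription factors (0.67 ± 0.15) and the phosphatase gene Dusp1 among 22 immediate early and stress genes (0.44 ± 0.09). These 4 lists passed camera (adjusted p = 0.0204, 0.0414, 0.000579 and 0.00448) but not with an estimated correlation (adjusted p = 0.214, 0.371, 0.214 and 0.214). Adjusted over the list alone, the counts were 8 lower for early NK genes, 5 higher for late maturation, 6 higher and 3 lower for core genes, 4 higher and 1 lower for cytotoxic genes, 6 higher for transcription factors and 4 higher for immediate early genes. With no member past edgeR's test on its own, camera placed the AP-1 and bZIP factors higher, and the T cell markers, neutrophil markers and ribosomal protein genes lower (adjusted p = 0.0354, 0.0303, 2.54e-05 and 3.01e-08). In that direction 4, 4, 2 and 1 of their members had an unadjusted p under 0.05. With an estimated correlation the adjusted p of these 4 lists was 0.214, 0.214, 0.214 and 0.501. Camera adjusted p-values of the lists that did not pass were 0.639 for heme and oxidative stress, 0.0888 for NK cell receptors, 0.785 for cytokine receptors, 0.579 for trafficking, 0.379 for ILC1-associated genes and 0.0573 for cell cycle. They were 0.548 for interferon response, 0.643 for glycolysis, 0.142 for cholesterol synthesis, 0.639 for B cell, 0.207 for myeloid and 0.643 for erythroid and platelet markers. With the replicate block the receptor and cell cycle lists passed (adjusted p = 0.0374 and 0.0277). Of single members of these lists, Klrb1b (0.82 ± 0.10), Klra9 (0.68 ± 0.15), Srxn1 (0.55 ± 0.12) and Ifit2 (0.66 ± 0.12) rose and Crtam (-0.78 ± 0.10) fell. The count of 70 was 128 with DESeq2 and 11 in a fit of the NK libraries alone, and 36, 44 and 44 without cWT NK replicate 1, cKO NK replicate 1 and cWT NK replicate 3.

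In iNK, Gzmb rose in the libraries labelled cKO from 204 ± 14.3 to 299 ± 9.20 CPM (0.55 ± 0.10, edgeR adjusted p = 0.0155, n = 3). Tcf7 (0.02 ± 0.10, adjusted p = 0.960) and Klrg1 (0.03 ± 0.16, adjusted p = 0.965) did not pass. The activation marker gene Cd69 (0.71 ± 0.10), Dusp1 (0.68 ± 0.09) and Zfp36, a regulator of mRNA decay (0.57 ± 0.12), rose. Largest among the higher genes were Adam8 (1.3 ± 0.23), Fcmr (1.17 ± 0.23), Hic1 (1.14 ± 0.23), Blk (1.06 ± 0.23) and Lpcat1 (0.98 ± 0.22), of which Fcmr and Blk are expressed by B cells. Serpine2 (-1.14 ± 0.16), Phlda3 (-0.98 ± 0.21), Clip4 (-0.94 ± 0.18), Cma1 (-0.86 ± 0.17) and Plscr4 (-0.67 ± 0.11) fell most. Of 36 called genes 26 were higher and 10 lower. Among 14 B cell markers only Blk passed the gene test, and Cd79a stood at 227 ± 74.9 CPM in cWT and 375 ± 118 CPM in cKO. Cd3e stood at 453 ± 36.3 and 490.0 ± 34.1 CPM. Camera placed the B cell markers, the immediate early and stress genes (2 rose of 22), the ILC1-associated genes (1 rose of 15, Cd69) and the AP-1 and bZIP factors higher (adjusted p = 7.95e-12, 6.24e-05, 0.00338 and 0.0108). With an estimated correlation the adjusted p was 0.0838, 0.119, 0.234 and 0.234. It placed the NK cell receptors and the ribosomal protein genes lower (adjusted p = 0.0108 and 5.81e-13, and adjusted p = 0.458 for both with an estimated correlation), although Klrb1b on the receptor list rose (0.78 ± 0.10). At an unadjusted p under 0.05, 8 receptors were lower and 2 higher of 28, and 0 of 36 ribosomal protein genes were lower. The counts adjusted over the list alone were 11 higher for B cells, 9 higher and 1 lower for immediate early genes, 4 higher for ILC1-associated genes and 1 higher for receptors. Of the AP-1 factors, which held no called member, 7 of 21 were higher at an unadjusted p under 0.05. With an estimated correlation 0 of the 6 lists passed. The count of 36 was 82 with DESeq2, 115 with voom, 67 with the replicate block and 5 in a fit of the iNK libraries alone. It was 18, 17 and 5 without cWT iNK replicates 1, 2 and 3, and 14 without cKO iNK replicate 1 or 2.

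In mNK1, Gzmb rose from 1136 ± 53.9 to 2374 ± 138 CPM in the libraries labelled cKO (1.06 ± 0.10, edgeR adjusted p = 1.97e-06, n = 3). Klrg1 rose from 184 ± 34.8 to 335 ± 9.58 CPM (0.86 ± 0.15), and Tcf7 fell (-0.49 ± 0.10). Entpd1 (1.89 ± 0.18), Ifi204 (1.43 ± 0.22), Kcnj8 (1.43 ± 0.18), Sgms1 (1.21 ± 0.27) and Itga1, which encodes the tissue-residency integrin CD49a (1.12 ± 0.21), rose most. Tnfsf8 (-1.83 ± 0.21), Gzmm (-1.49 ± 0.30), Tnfsf4 (-1.43 ± 0.25), Serpine2 (-1.35 ± 0.16) and Phlda3 (-1.3 ± 0.20) fell most. Called were 70 genes, 47 higher and 23 lower. Of 16 late maturation markers 4 rose, of 22 immediate early genes 2 rose, with Zfp36 at 0.77 ± 0.12, and of 14 B cell markers 1 rose, Ebf1, from 1 count over the 3 cWT libraries to 0.462 ± 0.342 CPM. These lists and the T cell markers, which held no called member and 3 higher ones at an unadjusted p under 0.05, passed camera upward (adjusted p = 8.94e-07, 9.30e-06, 2.68e-10 and 0.00172). They also passed with an estimated correlation (adjusted p = 0.0382 for each). Of 15 core NK genes 2 rose and 1 fell, of 20 early NK genes 3 fell, with Kit at -1.19 ± 0.22, and of 27 NK transcription factors 2 rose, with Rora at 0.84 ± 0.18. Of 18 heme and oxidative stress genes 1 rose, Srxn1 (0.60 ± 0.13). These 4 lists passed camera (adjusted p = 0.00267, 0.00567, 0.00142 and 0.01) but not with an estimated correlation (adjusted p = 0.108, 0.188, 0.233 and 0.214). Counts of members adjusted over the list alone were 8 higher for late maturation, 5 higher for immediate early genes, 9 higher for B cells, 7 higher and 2 lower for core genes, 4 lower for early NK genes, 7 higher for transcription factors and 1 higher for heme and oxidative stress. Without a called member, the AP-1 factors and myeloid markers passed upward and the ribosomal protein genes downward (camera adjusted p = 0.0123, 0.0127 and 3.14e-07, and adjusted p = 0.160, 0.520 and 0.520 with an estimated correlation). In these directions 5, 1 and 0 members had an unadjusted p under 0.05. With the replicate block the cell cycle list passed as well (adjusted p = 0.0823 without and 0.0111 with it). Outside the lists that passed, Cxcr6 (0.84 ± 0.16), Slc2a3 (0.47 ± 0.10) and Aldoa (0.36 ± 0.08) rose. The count of 70 was 126 with DESeq2, 147 with voom and 12 in a fit of the mNK1 libraries alone. It was 29, 32 and 35 without cWT mNK1 replicates 1, 2 and 3, and 28 and 26 without cKO mNK1 replicates 1 and 2.

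In mNK2, Tcf7 fell from 100.2 ± 7.41 to 45.6 ± 7.88 CPM in the libraries labelled cKO (-1.13 ± 0.10, edgeR adjusted p = 1.50e-06, n = 3). Gzmb rose from 4394 ± 185 to 7888 ± 1307 CPM (0.84 ± 0.10, adjusted p = 4.36e-05). Klrg1 did not pass (0.50 ± 0.15, adjusted p = 0.367). Higher with the largest folds were Ifit1bl1 (1.18 ± 0.23), Ttc39c (1.07 ± 0.11), Kcnj8 (0.89 ± 0.17), Gzmb and Entpd1 (0.82 ± 0.17). Kit (-1.72 ± 0.25), Gzmm (-1.62 ± 0.32), Phlda3 (-1.60 ± 0.21), Tnfsf4 (-1.51 ± 0.26) and Serpine2 (-1.49 ± 0.17) were lower. Called were 32 genes, 16 in each direction. Of 20 early NK genes 4 fell, Tcf7 and Kit among them (camera adjusted p = 4.43e-09, adjusted p = 0.0155 with an estimated correlation). Among the late maturation markers Gzmb rose, and among the NK cell receptors Klrb1b rose (0.72 ± 0.10) and Crtam fell (-0.82 ± 0.11). Both lists passed camera upward (adjusted p = 0.00443 and 0.0120), but not with an estimated correlation (adjusted p = 0.321 and 0.422). Adjusted over the list alone, the counts were 7 lower for early NK genes, 3 higher and 1 lower for late maturation and 4 higher and 1 lower for receptors. Without a called member, camera placed the NK transcription factors, heme and oxidative stress genes and B cell markers higher and the neutrophil markers and ribosomal protein genes lower (adjusted p = 0.0195, 0.0485, 2.80e-06, 0.000677 and 0.000342). In these directions 4, 1, 4, 2 and 0 members had an unadjusted p under 0.05, and with an estimated correlation the adjusted p was 0.490, 0.437, 0.301, 0.422 and 0.667. The trafficking gene Ccr2 fell (-0.35 ± 0.08) and Cd28 rose (0.51 ± 0.10). The count of 32 was 69 with DESeq2, 137 with voom and 62 with the replicate block, and 21, 21 and 18 without cWT mNK2 replicate 1, cWT mNK2 replicate 3 and cKO mNK2 replicate 2.

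**Figure D3:**
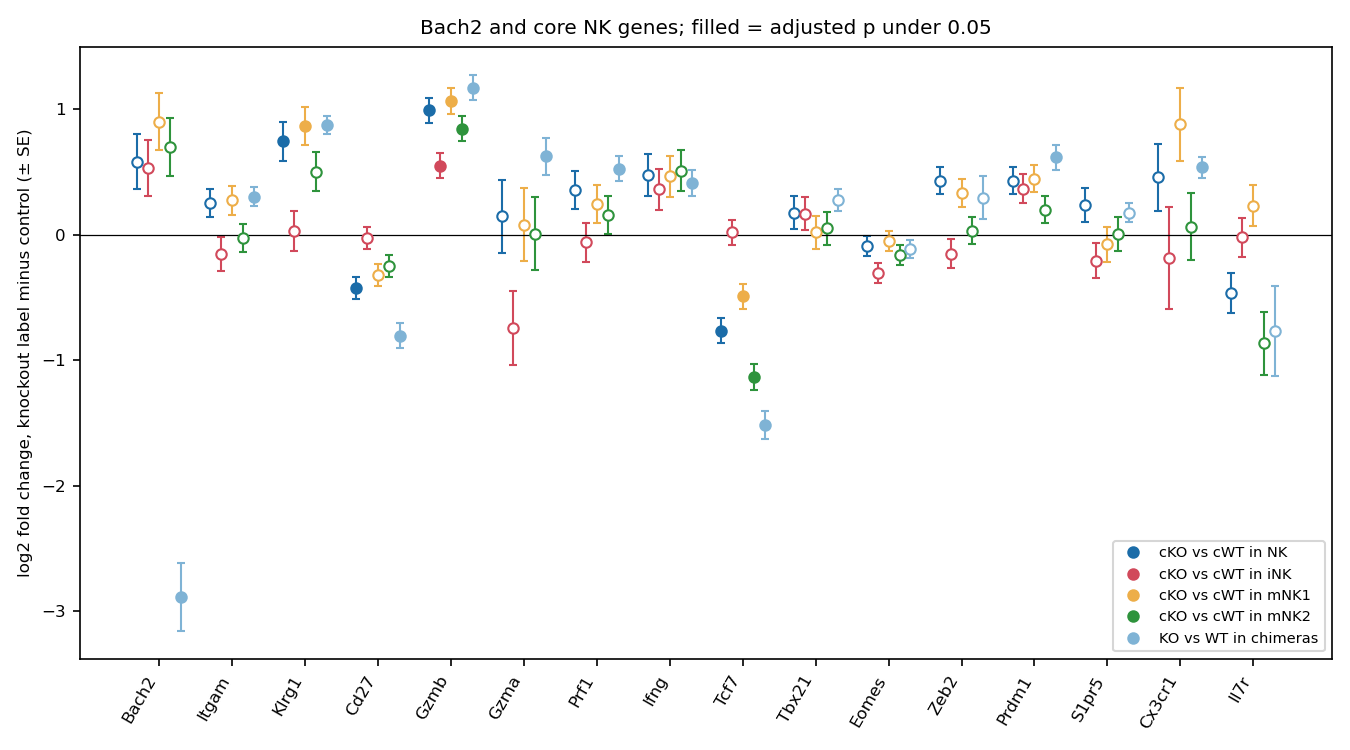
Log2 fold change ± SE of Bach2 and the 15 core NK genes (horizontal axis) in the 5 knockout comparisons, knockout label minus control; filled points have an edgeR adjusted p under 0.05. Gzmb is positive and filled in all 5 comparisons, and Bach2 is negative only in the chimeras.

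Whether the effect of the cKO label differed between the 4 fractions was asked with the interaction of genotype and fraction. Tcf7 did so (adjusted p = 0.00477), with log2 fold changes of -0.77 in NK, 0.02 in iNK, -0.49 in mNK1 and -1.13 in mNK2. Gpr183, a receptor for oxysterols that guides lymphocytes (adjusted p = 0.00698), stood at -0.20, 0.33, 0.26 and -1.26 in the same order. Cd69 (adjusted p = 0.0323) stood at -0.10, 0.71, 0.02 and -0.11, and the receptor gene Lilr4b (adjusted p = 0.0402) at 0.29, 0.96, 0.84 and -0.47. Gpr183 and Lilr4b are named after their values were seen. The sum of the B cell markers stood at 2132 CPM in cWT and 3823 CPM in cKO iNK, against 379 and 387 CPM in NK. In mNK1 it stood at 253 and 475 CPM and in mNK2 at 180 and 261 CPM. Whether reads of other cells enter the iNK values of these 4 genes was not tested. These 4 genes were the edgeR calls, with 484 at an unadjusted p under 0.05, against 38 calls with the DESeq2 likelihood ratio test, 21 with the replicate block and 8 without a low-count filter. With single libraries left out the count ran from 2 to 12, beyond 1.5 times the 4 in 9 of 24 fits, of which 12 came without cKO mNK1 replicate 3. The interaction of Klrg1 (adjusted p = 0.775) and of Gzmb (adjusted p = 0.838) did not pass, so a difference between fractions is not shown for them.

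Calls in the 5 knockout comparisons overlapped beyond chance. Gzmb, Klrb1b and Ttc39c rose in all 5. In at least 4, 13 genes rose, which adds Dusp1, Entpd1, Gpc1, Kcnj8, Klf6, Meis3, Ptger4, Rgs1, Smpdl3a and Tnfaip3, and 6 fell, among them Crtam, Kit, Serpine2, Tcf7 and Tnfsf8. Of these, Klf6, the NF-kB inhibitor gene Tnfaip3, Dusp1 and Rgs1 were called in the 4 conditional comparisons but not in the chimeras. There they stood at 0.07, -0.15, 0.40 and 0.40. Serpine2, lower in the 4 fractions, stood at 0.87 in the chimeras. The immediate early and stress list passed camera in NK, iNK and mNK1, but not in mNK2 or the chimeras (camera adjusted p = 0.184 and 0.294). The NK fraction and the chimeras, which have no library in common, shared 23 higher calls (0.974 expected) and 15 lower calls (0.618 expected). For mNK1 and the chimeras these numbers were 29 (1.21) and 11 (0.523), for mNK2 10 (0.421) and 11 (0.357), and for iNK 7 (0.658) and 0 (0.214). By Fisher's exact test the overlap passed for 19 of the 20 pairs and directions, with iNK and the chimeras in the lower direction as the exception (p = 1). The expected counts assume independent comparisons, which is not shown for the 12 tests between conditional fractions, since their libraries are not known to come from different animals.

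The WT subsets show how expression differs between libraries sorted along maturation in unmodified animals. Markers of T, B and myeloid cells differed between these libraries too. Whether reads of such cells enter the other changes along these steps was not tested. From iNK to mNK1, Itgam (3.93 ± 0.13), Gzmb (2.61 ± 0.13, from 98.9 ± 24.4 to 603 ± 59.4 CPM), Gzma (2.14 ± 0.12) and Prdm1 (1.59 ± 0.14) rose, and Il7r (-3.61 ± 0.23) and Tcf7 (-1.34 ± 0.12) fell. Among 16 late maturation markers 13 rose and 1 fell, of 19 early NK genes 2 rose and 14 fell, and of 15 ILC1-associated genes 14 fell, with Ltb at -1.97 ± 0.12. Of 13 T cell markers 9 fell, with Cd3e at 119.5 ± 28.8 CPM in iNK and 3.67 ± 1.02 in mNK1. These lists and the core genes (10 rose and 3 fell of 15) passed camera (adjusted p = 8.92e-17, 2.57e-09, 7.41e-16, 1.32e-11 and 4.31e-10), also with an estimated correlation. The counts adjusted over the list alone were 14 higher and 1 lower for late maturation, 2 higher and 14 lower for early NK genes, 15 lower for ILC1-associated genes, 9 lower for T cells and 11 higher and 3 lower for core genes. The other genes with the largest falls were Tdrp (-5.62 ± 1.08), Gpr55 (-6.57 ± 0.76), Apol7b (-5.22 ± 0.97) and the dendritic cell factor gene Batf3 (-5.59 ± 0.59). Myeloid transcripts stood on the higher side, with S100a9 at 0.0232 ± 0.0464 CPM in iNK and 19.3 ± 17.4 in mNK1, S100a8 (7.25 ± 1.44), Csf1r (5.28 ± 1.09), C1qb (5.22 ± 1.08) and Vcam1, at 0.0528 and 6.81 CPM. The Vcam1 mean in mNK1 leaned on replicate 4, at 20.2 CPM against 1.66 to 2.97 in the other libraries. Of 9 myeloid markers 3 rose, and of 8 neutrophil markers 4 rose. Both lists passed camera (adjusted p = 4.52e-06 and 0.000107), but not with an estimated correlation (adjusted p = 0.0990 and 0.178). The cytotoxic, transcription factor and trafficking lists (upward) and the ribosomal protein and B cell lists (downward) also passed with the preset correlation alone (adjusted p = 0.106 to 0.218 with an estimated correlation). Called were 1163 of 11051 genes, 706 higher and 457 lower.

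From mNK1 to KLRG1-negative mNK2, 22 fell of 33 cell cycle genes, with the proliferation marker Mki67 at -3.29 ± 0.30, Top2a at -2.76 ± 0.24 and Ccna2 at -4.83 ± 0.45. Of 19 early NK genes 12 fell, with Ltb at -3.51 ± 0.14, Tcf7 at -2.30 ± 0.13 and Cd27 at -1.90 ± 0.13. Of 16 late maturation markers 13 rose and 1 fell, with Ly6c2 at 2.09 ± 0.12, Gzmb at 1.31 ± 0.12 and Zeb2 at 1.17 ± 0.16. Of 26 interferon response genes 9 fell, of 15 ILC1-associated genes 7 fell and of 13 T cell markers 7 fell. These 6 lists passed camera (adjusted p = 2.84e-28, 9.88e-18, 6.15e-16, 1.06e-05, 1.10e-11 and 5.19e-12), also with an estimated correlation. Counts of members adjusted over the list alone were 28 lower for cell cycle, 14 lower for early NK genes, 14 higher and 1 lower for late maturation, 9 lower for interferon response, 10 lower for ILC1-associated genes and 9 lower for T cells. Gpx8 (3.18 ± 0.37), Cdc42ep1 (2.61 ± 0.60), Cx3cr1 (2.45 ± 0.34), Cdc20b (2.32 ± 0.21) and Ube2l6 (2.23 ± 0.43) had the largest rises. Ncapg fell (-4.81 ± 0.57), as did Vcam1, from 6.81 to 0.0961 CPM, a call that ended (adjusted p = 0.0816) without WT mNK1 replicate 4, which held 20.2 CPM. Csf2rb and the long noncoding RNA Tmevpg1 fell from 5.42 and 7.32 CPM to 1 count each over the 4 libraries. The core list (upward) and the cytokine receptor, trafficking, ribosomal protein, B cell and myeloid lists (downward) passed camera with the preset correlation alone (adjusted p = 0.0912 to 0.353 with an estimated correlation). The call of the trafficking list ended with the replicate block (adjusted p = 0.0592). Called were 806 genes, 241 higher and 565 lower, and 954 with the replicate number as a block.

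Between the mNK2 subsets sorted by KLRG1, Klrg1 itself rose from 177 ± 40.1 to 1185 ± 87.8 CPM (2.74 ± 0.16, edgeR adjusted p = 4.65e-10, n = 4). Cx3cr1 (2.56 ± 0.31), Klra9 (1.03 ± 0.09) and Gzmb (0.51 ± 0.12) rose, and Tcf7 (-1.37 ± 0.14), Cd27 (-1.24 ± 0.14) and the chemokine receptor gene Cxcr3 (-1.64 ± 0.15) fell. In the KLRG1-positive cells 15 rose of 33 cell cycle genes, led by Ccna2 (4.26 ± 0.44), Bub1b (3.0 ± 0.54) and Birc5 (2.88 ± 0.43). Fam81a (3.46 ± 0.71) and Ccl9 (2.98 ± 0.37) rose as well. Tuba8 (-3.0 ± 0.52), Emb (-2.27 ± 0.26), Kbtbd11 (-2.14 ± 0.21), Dpysl5 (-2.0 ± 0.41) and Airn (-1.88 ± 0.41) fell. Airn is an antisense RNA of Igf2r, and counts without a known strand setting do not separate them. Among 16 late maturation markers 6 rose, of 19 early NK genes 8 fell and of 15 ILC1-associated genes 3 fell. With the cell cycle genes, these lists passed camera (adjusted p = 3.01e-26, 1.71e-12, 5.98e-14 and 0.000812), also with an estimated correlation. Adjusted over the list alone, the counts were 16 higher for cell cycle, 13 higher and 1 lower for late maturation, 9 lower for early NK genes and 1 higher and 5 lower for ILC1-associated genes. The ribosomal protein and neutrophil lists, both downward, passed with the preset correlation alone (camera adjusted p = 3.00e-06 and 2.63e-05, adjusted p = 0.397 and 0.283 with an estimated correlation). Called were 150 genes, 81 higher and 69 lower, against 256 with DESeq2 and 198 with the replicate number as a block.

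Over the whole span from iNK to KLRG1-positive mNK2, 3382 genes differed, 1655 higher and 1727 lower, and 409 and 893 of them by 2-fold or more. Gzmb (4.43 ± 0.14), Itgam (5.04 ± 0.13) and Klra9 (2.79 ± 0.10) rose, and Tcf7 (-5.02 ± 0.14), Ltb (-7.09 ± 0.17) and Crtam (-4.17 ± 0.20) fell. Of the named genes with counts in both groups, Gpx8 had the largest rise (8.13 ± 0.49). Sema6a, Smpdl3b, Chit1 and Pth1r rose to 7.12, 7.90, 12.8 and 6.70 CPM from 2 counts or fewer over the 4 iNK libraries. Tmevpg1, Cd5, Cd3e, Gpr55 and Bmp7 fell from 36.3, 27.3, 119.5, 23.5 and 45.9 CPM to 2 counts or fewer per group. Of 16 late maturation markers 15 rose and 1 fell, of 19 early NK genes 17 fell, of 15 ILC1-associated genes 14 fell, of 15 core genes 10 rose and 3 fell and of 13 T cell markers 12 fell. These lists passed camera (adjusted p = 4.53e-19, 7.48e-18, 1.95e-15, 5.67e-06 and 5.11e-13), also with an estimated correlation. The counts adjusted over the list alone were 15 higher and 1 lower for late maturation, 18 lower for early NK genes, 14 lower for ILC1-associated genes, 10 higher and 3 lower for core genes and 13 lower for T cells. The cytotoxic list (upward) and the cell cycle, interferon, ribosomal protein and B cell lists (downward) passed with the preset correlation alone (adjusted p = 0.0537 to 0.285 with an estimated correlation).

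The same steps were compared within the cWT libraries. Markers of B and T cells differed here as well, with a B cell marker sum of 2132 CPM in iNK against 253 CPM in mNK1. Whether reads of other cells enter the changes of the cWT steps was not tested. Against the NK fraction, cWT iNK had lower Itgam (-5.38 ± 0.14), Gzmb (-3.29 ± 0.11), Gpx8 (-5.32 ± 0.38), Rhpn1 (-5.17 ± 0.32) and Cx3cr1 (-4.96 ± 0.35). Higher were Il7r (2.80 ± 0.17), Tcf7 (1.45 ± 0.10), Cxcr6 (2.78 ± 0.15), Ly6c1 (3.40 ± 0.50), Adam19 (3.32 ± 0.46), Actn1 (3.30 ± 0.44), Prss12 (3.30 ± 0.38) and Pacsin1 (3.28 ± 0.48). The neutrophil gene Ngp stood at 16.7 ± 12.8 CPM in NK and at 1 count over the 3 iNK libraries. Among 16 late maturation markers 1 rose and 15 fell, of 15 core genes 3 rose and 11 fell and of 24 cytotoxic genes 3 rose and 10 fell. Of 20 early NK genes 16 rose and 1 fell and of 15 ILC1-associated genes 12 rose, and all 14 B cell and all 14 T cell markers tested rose with them. These 7 lists passed camera (adjusted p = 3.40e-22, 1.60e-10, 4.59e-05, 5.84e-13, 3.10e-10, 9.25e-16 and 9.71e-14), also with an estimated correlation. Counts of members adjusted over the list alone were 1 higher and 15 lower for late maturation, 3 higher and 11 lower for core genes, 3 higher and 11 lower for cytotoxic genes, 16 higher and 1 lower for early NK genes, 12 higher for ILC1-associated genes, 14 higher for B cells and 14 higher for T cells. Transcription factor, receptor and neutrophil lists (downward) and cell cycle, interferon and ribosomal protein lists (upward) passed with the preset correlation alone (adjusted p = 0.170 to 0.444 with an estimated correlation). This is the comparison in which the residual correlation of every same-number pair exceeded 0.1, which does not show the other comparisons to be unpaired. With the number as a block 3108 genes were called against 2916 (1477 higher, 1439 lower). The block carried the myeloid (camera adjusted p = 0.0503 without and 0.00499 with it) and erythroid lists (0.0558 and 0.0455) across the threshold, both upward.

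From cWT iNK to mNK1, Itgam (4.72 ± 0.14), Gzmb (2.48 ± 0.11) and Prdm1 (1.78 ± 0.12) rose. Cxcr6 (-4.94 ± 0.17), Il7r (-4.22 ± 0.18), Drc1 (-7.22 ± 0.51), Slc16a5 (-5.58 ± 0.72) and Rasgrp3 (-5.44 ± 0.57) fell. Cd3e fell from 453 ± 36.3 to 8.98 ± 1.34 CPM, and Ebf1, a B cell factor gene, from 6.0 CPM to 1 count over the 3 libraries. The genes of neutrophil granules Ngp, Ltf, S100a9, Lcn2 and Camp, with 1 count or fewer over the 3 iNK libraries, stood at 59.8 ± 51.0, 15.9 ± 13, 12.8 ± 12.6, 8.10 ± 7.81 and 7.70 ± 8.59 CPM in mNK1. All 14 B cell and all 14 T cell markers tested fell. Of 16 late maturation markers 14 rose and 1 fell, of 15 core genes 11 rose and 3 fell, of 24 cytotoxic genes 12 rose and 2 fell, of 20 early NK genes 2 rose and 14 fell and of 15 ILC1-associated genes 12 fell. These 7 lists passed camera (adjusted p = 3.70e-26, 2.32e-19, 6.64e-16, 2.01e-09, 1.89e-07, 4.31e-09 and 1.76e-12), also with an estimated correlation. Adjusted over the list alone, the counts were 14 lower for B cells, 14 lower for T cells, 14 higher and 1 lower for late maturation, 11 higher and 3 lower for core genes, 12 higher and 2 lower for cytotoxic genes, 3 higher and 15 lower for early NK genes and 13 lower for ILC1-associated genes. Transcription factors, receptors, immediate early genes and neutrophil markers (upward) and ribosomal protein genes (downward) passed with the preset correlation alone (adjusted p = 0.0777 to 0.640 with an estimated correlation). Of 2271 called genes, 1255 were higher and 1016 lower. Those tested in both experiments shared 434 higher (72.9 expected) and 268 lower calls (37.5 expected) with the WT step from iNK to mNK1, with 1 and 2 in the opposite direction.

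From cWT mNK1 to mNK2, 32 fell of 33 cell cycle genes, with Ccna2 at -3.66 ± 0.28 and Cenpf at -2.98 ± 0.28. Cd27 (-2.09 ± 0.09), Tcf7 (-1.92 ± 0.10), Clec4n (-3.98 ± 1.23), Ankle1 (-3.94 ± 0.54), Tmevpg1 (-6.68 ± 0.68) and the iron exporter gene Slc40a1 (-3.79 ± 0.96) fell. Gzmb (1.95 ± 0.10), Prf1 (1.71 ± 0.16), Zeb2 (1.82 ± 0.11), Cdc42ep1 (5.0 ± 0.48), Gpx8 (3.98 ± 0.31), Rhpn1 (3.88 ± 0.27), Cx3cr1 (3.66 ± 0.30) and Parm1 (3.61 ± 0.40) rose. Among 16 late maturation markers 15 rose, of 15 core genes 10 rose and 3 fell, of 20 early NK genes 16 fell, of 15 ILC1-associated genes 10 fell and of 14 T cell markers 11 fell. With the cell cycle genes, these lists passed camera (adjusted p = 4.66e-28, 9.02e-22, 4.31e-06, 5.66e-17, 1.20e-08 and 1.99e-09), also with an estimated correlation. The counts adjusted over the list alone were 32 lower for cell cycle, 15 higher for late maturation, 10 higher and 3 lower for core genes, 17 lower for early NK genes, 11 lower for ILC1-associated genes and 12 lower for T cells. Transcription factors (upward) and interferon, ribosomal protein and myeloid lists (downward) passed with the preset correlation alone (adjusted p = 0.177 to 0.534 with an estimated correlation). Of 2481 called genes, 944 were higher and 1537 lower.

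Whether the knockout libraries lay further along this path was asked with the 409 genes that rose and the 893 that fell by 2-fold or more over that whole span in the WT experiment. Its libraries are separate from both knockout experiments. In unfractionated libraries these sets do not separate a changed mixture of NK stages from a change within cells. In the chimeras, 85 of 394 tested members of the higher set rose and 2 fell (127 and 5 adjusted over the list alone), with a median log2 fold change of 0.24. Rhpn1 (1.43 ± 0.12) and Klrg1 rose, and Avil (-1.68 ± 0.24) and Parm1 (-1.41 ± 0.39) fell. Of 800 members of the lower set 137 fell and 13 rose (198 and 20 adjusted over the list alone), with a median of -0.26. Tcf7 and the T cell gene Cd3d (-2.70 ± 0.19) fell, and Lilr4b (1.80 ± 0.17) and Rora rose. B and T cell markers fell in the same libraries, 12 of 12 and 7 of 10 adjusted over the list alone. Camera gave adjusted p-values of 1.14e-22 and 6.74e-16 for the higher and lower set, and 0.00568 and 0.0294 with an estimated correlation. In the NK fraction of the libraries labelled cKO, 15 of 404 members of the higher set rose and 1, Serpine2, fell (39 and 3 adjusted over the list alone), with a median of 0.16. Of 883 members of the lower set 18 fell and 1, Hic1 (1.04 ± 0.23), rose (48 and 5 adjusted over the list alone), with a median of -0.21. Over the 137 members at 20 CPM or more in KLRG1-positive mNK2, a choice made after the data were seen, the median was -0.252 (bootstrap interval -0.322 to -0.192). T cell markers, some of them members of this set, passed camera downward in the same libraries. Camera gave an adjusted p of 3.69e-12 for both sets, and 0.00356 and 0.00174 with an estimated correlation.

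In mNK1 of the libraries labelled cKO, 13 members of the higher set rose and 1 fell (45 and 5 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 2.49e-07, adjusted p = 0.0390 with an estimated correlation). Of the lower set 11 fell and 8 rose (24 and 16 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.0410, adjusted p = 0.251 with an estimated correlation). That call ended with the replicate block (median -0.0754) and without cWT mNK1 replicate 1, cKO mNK1 replicate 1 or cKO mNK1 replicate 3 (medians -0.0438, -0.0806 and -0.0709). Over the same 137 members the median was -0.222 (bootstrap interval -0.269 to -0.146). B and T cell markers, which were lower in the mature WT libraries than in iNK, passed upward in mNK1. The sum of the B cell markers was higher by 87.6%. In mNK2, 4 members of the higher set rose and 1 fell, with the same numbers adjusted over the list alone and a median of 0.05 (camera adjusted p = 4.01e-05, adjusted p = 0.0609 with an estimated correlation). Of the lower set 10 fell and 2 rose (23 and 3 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 2.65e-06, adjusted p = 0.0247 with an estimated correlation). Without cWT mNK2 replicate 1 the medians of the higher and lower set were 0.0227 and -0.0612, and both sets passed. In iNK neither set passed (medians 0.04 and 0.03, camera adjusted p = 0.874 for both), and camera's direction for the higher set was downward although its median was positive. With single libraries left out these medians ran from -0.0176 to 0.0229 and from -0.000527 to 0.0189, and neither set passed. Over the members at 20 CPM or more, the lower set changed direction in iNK and passed (median -0.107, bootstrap interval -0.170 to -0.0315, camera adjusted p = 0.00864). The sum of the B cell markers was higher by 79.3% in cKO iNK. Of the higher set 2 members rose and 4 fell in iNK (3 and 7 adjusted over the list alone), and of the lower set 9 rose (20 adjusted over the list alone), Cd69 and Lilr4b among them.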

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

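Chosen after the result was seen were the tests of exchanged labels, of B cells (both), of exons outside the deleted part, of neighbours among the calls with the smallest p and of the rise of NK genes.

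Bach2 had more reads in the libraries labelled cKO than in cWT in each of the 4 fractions, the reverse of what a lost transcript would give. An exchange of the cWT and cKO labels in the NK fraction is argued against by the chimera calls: 68.7% of the higher ones (exact interval 62.9% to 74.1%) were positive and 82.8% of the lower ones (77.5% to 87.3%) were negative there, while the shares were 75.5% and 45.2% in iNK, 89.2% and 64.8% in mNK1 and 57.2% and 70% in mNK2, so that in iNK the lower calls do not argue against it. B cells as the whole source in NK, mNK1 and mNK2 are argued against, since the sum of B cell markers was higher by only 2.33% in NK (379 ± 31.7 and 387 ± 37.3 CPM), and since Bach2 was higher by 52.5 and 91.0 CPM per 1000 CPM of added marker reads in mNK1 and mNK2, against 3.56 in iNK. In iNK the marker sum was higher by 79.3%, so B cells could carry Bach2 reads there, and that stays open. Open as well is whether the gene count, 1.5-fold in NK, may hold exons outside the deleted part, since the counts are per gene, and a feedback of Bach2 on its own gene was not tested.

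Some calls of the chimera comparison sit next to each other in the genome, which a strain or donor difference between the 2 marrows could produce. The densest window of 20 tested neighbours held 7 calls, equal to the 95th percentile of 1000 shuffles (p = 0.0919, permutation test, 1 of 12 comparisons scanned), and among the 50 calls with the smallest p the densest held 3 (p = 0.129), but 5 in windows of 50 (p = 0.00400) and of 100 genes (p = 0.0320). In windows of 50 the 5 lie on chromosome 11, with log2 fold changes in the chimeras and in conditional NK of -3.42 and -0.47 for Pik3ip1 and -4.25 and 0.56 for Camk2b, both called in conditional NK, and of 1.16 and 0.00 for Tcn2, -1.71 and -0.08 for Pes1, and -2.37 and -0.05 for Emid1, which were not. In windows of 100, chromosomes 6 and 9 also reached 5, and there Klrb1b, Klrg1, Cd27, Klra9 and Crtam were called in conditional NK in the direction of the chimeras, which goes against a difference of the chimera marrows for these genes, while C3ar1, Cyp11a1, Pou2af1, Cd3d, Cd3e and Cd3g were not called there. The explanation stays open, because the bound set beforehand, no more calls than the 95th percentile, was met only by equality. Wider windows also pass among the 50 calls with the smallest p, and the gene order comes from another build (99.8% of genes placed). This reading was adopted after the values were seen. In the scan of all calls in windows of 20, WT maturation steps with no marrow difference had dense windows too (permutation p = 0.000999 for mNK1 to KLRG1-negative mNK2, the smallest p the shuffles can give). Dense windows in that scan therefore need no marrow difference. The scan of the 50 calls with the smallest p was run only for the chimeras, so the WT steps do not bear on the chromosome 11 genes.

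Markers of B and T cells were lower and those of neutrophils and myeloid cells higher in the chimera KO libraries, so a different admixture of other cells may enter that comparison. Loss of B and T cells as the source of the lower maturation set is argued against: its 137 members that KLRG1-positive mNK2 cells express at 20 CPM or more had a median of -0.278 (bootstrap interval -0.314 to -0.242). A smaller share of other cells would raise all NK genes alike. The log2 fold changes of Gzmb and Klrg1 exceeded the highest among the 5 core NK genes not called (Zeb2, 0.29) by 0.876 and 0.576 (interval for Klrg1 0.210 to 0.942). For Prf1 the excess was 0.231 (interval -0.160 to 0.622). That reference came from genes without a call, while these genes were called, so the excess is partly set by the choice. The core genes did not change alike, with Eomes at -0.12 ± 0.07, Itgam at 0.30 ± 0.08 and Gzma at 0.62 ± 0.15 beside Gzmb at 1.17 ± 0.10. A common rise alone would not give this spread, but its part in the rise of Gzmb, Klrg1 and Prf1 stays open. The share of other cells itself was not measured. The B, T and myeloid genes among the calls themselves stay open between admixture, a changed mixture of NK stages and the knockout, which the design does not separate. For Gzmb, Klrg1, Prf1, Tcf7, Cd27 and the maturation sets in the chimeras, a changed mixture of NK stages stays open as well.

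Single libraries stood far from the other 3 of their group in 23 of 266 values tested. In 17 of them the other libraries held no reads, so that any read sets the library apart, and the values under 0.252 CPM lie below the detection floor of the WT libraries. The remaining 6 are fewer than the 13.3 that chance gives over all 266 values, a base from which the 17 were not removed. The full 23 are more than 13.3, so an excess of outlying libraries is neither shown nor excluded. With no reads in the other libraries, the values in WT iNK were S100a9 (0.0928 CPM), S100a8 (0.371), Csf1r (1.02) and Gpx8 (0.835) in replicate 4, Vcam1 (0.211) and Sema6a (0.106) in replicate 2, Smpdl3b and Pth1r (0.0895 each) in replicate 3 and Chit1 (0.215) in replicate 1. In WT mNK1 they were Gpr55 (0.934) in replicate 4, Tdrp (0.623) in replicate 1 and Pth1r (1.3) in replicate 3. In KLRG1-negative mNK2 they were Vcam1 (0.384) and Csf2rb (0.0961) in replicate 4 and Tmevpg1 (0.0974) in replicate 3, and in KLRG1-positive mNK2 Vcam1 (0.660) in replicate 2 and Bmp7 (0.111) in replicate 4. The others were Ccna2 in WT iNK replicate 1 (24.4 against 12.3 to 13.7 CPM), Vcam1 in WT mNK1 replicate 4 (20.2 against 1.66 to 2.97), Smpdl3b in WT mNK1 replicate 3 (0 against 2.39 to 2.60), Csf1r in KLRG1-positive mNK2 replicate 4 (7.96 against 3.41 to 3.67), Il7r in chimera KO replicate 3 (24.7 against 9.36 to 10.8) and Rab44 in chimera KO replicate 4 (4.68 against 16.4 to 18.3).

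The effect of the cKO label differed between the fractions for Tcf7 (interaction adjusted p = 0.00477), Gpr183 (0.00698), Cd69 (0.0323) and Lilr4b (0.0402). Whether other cells in the iNK libraries enter these values was not tested.

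With 3 libraries against 3, the 10 splits are too few for a share under 0.05. The real split, the 1 with as many calls in each case, and the highest other gave 70 and 1 calls in NK, 36 and 1 in iNK, 70 and 0 in mNK1 and 32 and 0 in mNK2. For the cWT steps they gave 2916 and 0 (iNK against NK, also among splits that part all pairs of replicate numbers), 2271 and 0, and 2481 and 0. With 4 against 4, the real split was the 1 of 35 with as many calls. That share is under 0.05, but it is the smallest that 35 splits can give. It was not adjusted over the comparisons, and splits that mix 2 differing groups widen the spread, so chance is not excluded. The counts were 1163 calls against 5 from WT iNK to mNK1, and 806 against 1, 150 against 1 and 3382 against 1 in the later steps and the whole span. In the chimeras they were 531 against 88, where the 88 came with KO replicates 1, 2 and 3 set beside WT replicate 1. For the interaction 2 of 100 splits gave 4 calls or more, the real one included. The other one called 11 genes, more than the real 4, which points to some structure among the libraries. These splits exchanged genotype labels within each fraction without regard to replicate number. They thereby also removed any effect common to the fractions, so they do not test an equal effect in all fractions, and chance is not excluded.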

How the results depend on the processing

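Chosen after the data were seen were the tests without Rn45s and with set members at 20 CPM or more, and all other alternatives were fixed before the data were examined. Of the results on counts and sets, 300 values under an alternative stayed on their side of the threshold or within 1.5 times the count, 59 moved, 8 lost the threshold and 1 changed direction. Of the values for single named genes 11766 kept their side, 662 lost the call (519 of them with a library left out and 84 in fits of only the 2 groups compared), 47 gained it and 0 reversed. A change of direction, for sets that given by camera, was counted only where the main or the other fit passed. The iNK set medians that changed sign with a library left out are therefore not among them. Where a fit leaves out libraries or pools fewer groups, fewer samples set the spread, and otherwise the cause was not tested.

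With DESeq2 the calls were 128 in conditional NK, 82 in iNK, 126 in mNK1, 69 in mNK2, 256 between the mNK2 subsets and 38 for the interaction. Voom with quality weights gave 115 in iNK, 147 in mNK1 and 137 in mNK2. Fits of only the 2 groups gave 11 in NK, 5 in iNK and 12 in mNK1. The replicate block gave 67 in iNK, 62 in mNK2 and 21 for the interaction, and no low-count filter gave 8 for the interaction. All calls of the main analysis in NK, iNK and mNK2 (70, 36 and 32) and 69 of 70 in mNK1 were among those of DESeq2, all with the same sign. Voom kept 57 of 70 in NK, 34 of 36 in iNK, 67 of 70 in mNK1 and 32 of 32 in mNK2, and fits of only the 2 groups kept 11 of 70, 4 of 36, 12 of 70 and 22 of 32.

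With an estimated correlation, 2 of 10 lists passed in NK, 0 of 6 in iNK, 4 of 11 in mNK1, 1 of 8 in mNK2 and 0 of 13 in the chimeras. For the cWT steps 7 of 13, 7 of 12 and 6 of 10 passed, and for WT 5 of 12 (iNK to mNK1), 6 of 12 (to KLRG1-negative mNK2) and 5 of 10 (the whole span). With the block 10 lists passed in iNK, which adds transcription factors (adjusted p = 0.0469), heme and oxidative stress (0.0469), cytokine receptors (0.0426) and myeloid markers (0.0133). The block also added receptors and cell cycle in NK, cell cycle in mNK1, myeloid and erythroid markers from cWT NK to iNK and receptors from WT iNK to mNK1 (0.0420), and ended the trafficking call from WT mNK1 to KLRG1-negative mNK2 (0.0592). Shared calls became 20 higher and 16 lower for NK and mNK2, 4 lower for iNK and mNK1, 16 higher and 2 lower for iNK and the chimeras (Fisher's exact adjusted p = 0.0795 for the latter) and 16 higher for mNK2 and the chimeras.

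The lower maturation set in mNK1 (median -0.0707) did not pass with an estimated correlation (adjusted p = 0.251), with fry (0.272) or with the block (-0.0754, adjusted p = 0.0549). The higher set in mNK2 (median 0.0485) did not pass with an estimated correlation (0.0609) or fry (0.147). With members at 20 CPM or more, the lower set in iNK changed direction, to a median of -0.107 (adjusted p = 0.00864).

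Leaving out each library in turn gave 36 to 69 calls in NK, 5 to 25 in iNK, 26 to 92 in mNK1, 18 to 26 in mNK2, 383 to 672 in the chimeras and 2 to 12 for the interaction. The cWT steps gave 2329 to 2556, 1759 to 2010 and 1792 to 2526, and the WT steps 863 to 1309, 612 to 690, 107 to 185 and 2948 to 3368. Counts moved by over 1.5 times in NK without cWT replicate 1 (36), cKO replicate 1 (44) or cWT replicate 3 (44), and in iNK without cWT replicate 1 (18), 2 (17) or 3 (5) or cKO replicate 1 or 2 (14 each). In mNK1 they did so without cWT replicate 1 (29), 2 (32) or 3 (35) or cKO replicate 1 (28) or 2 (26), and in mNK2 without cWT replicate 1 or 3 (21 each) or cKO replicate 2 (18). The interaction had 2 calls without cKO iNK replicate 1 or 2, cKO mNK2 replicate 1, cKO NK replicate 3, or replicate 2 of cWT NK, iNK or mNK1, and 7 and 12 without cKO mNK1 replicate 1 and 3.

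Medians of the higher set ran from 0.130 to 0.186 in NK, -0.0176 to 0.0229 in iNK, 0.119 to 0.169 in mNK1, 0.0227 to 0.0596 in mNK2 and 0.216 to 0.254 in the chimeras. Those of the lower set ran from -0.263 to -0.165, -0.000527 to 0.0189, -0.0951 to -0.0438, -0.187 to -0.0612 and -0.299 to -0.208 in the same order. In mNK1 the lower set did not pass without cWT replicate 1 (-0.0438, adjusted p = 0.200), cKO replicate 1 (-0.0806, 0.0618) or cKO replicate 3 (-0.0709, 0.105). Medians in mNK2 without cWT replicate 1 were 0.0227 and -0.0612, and both sets passed. A count of 3 in 1 library stands for up to 0.220 CPM in the conditional, 0.334 in the WT and 0.351 in the chimera libraries, and differences below that level are not detectable. Simulated 1.5-fold changes were recovered for 49.3%, 38.8% and 61.2% of genes in the conditional NK, WT iNK to mNK1 and chimera designs. They were placed only in genes at a mean of 5 CPM or more. The designs differ in depth, number and spread of libraries, and no share of the difference in recovery was assigned to depth.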
